A study of Mus musculus with 11 samples.

How the data were processed

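Gene expression was measured on 11 Affymetrix mouse ST arrays, 1 per sample, in tissue from CD1 mouse embryos at E8.5. Per the labels' protocols, embryos were frozen and cut on a cryostat, cells were taken by laser capture microdissection on an Arcturus Veritas, RNA was prepared with a Zymo kit and amplified with the NuGEN Ovation Pico system, and the product was labelled with biotin. The groups were taken from the labels: 3 arrays of neuroepithelium, 5 of neural crest and 3 of paraxial mesoderm. The series speaks of single cells, whereas the labels tie no array to a number of cells or to an embryo. If arrays of one tissue shared embryos, the p-values given here are too small, and if arrays of different tissues did, they may be too large. If each array held 1 cell with no embryo named, each tissue would count as 1 sample and no test between tissues would hold. The p-values therefore measure only the spread between these arrays, and values per array stand beside them.

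RMA, a summary of probe intensities on the log scale, and the genome build mm9 are named without a version, per the submitters' processing notes. The deposited values are not RMA log intensities: each is a linear ratio to a reference value of its own probe. The column medians were 1 on 8 arrays, 1.00 on neuroepithelium array 2, 0.991 on neural crest array 3 and 1.01 on neural crest array 5. A value of exactly 1 (within 1e-05) occurred on 1 of those 8 arrays for 26158 probes, with 3 or 4 of the other such arrays below it for 26155 of them, and 2698 probes had no array at 1 and 4 of the 8 below. The reference is thus the probe's median over 9 arrays, the 8 and 1 more that is not given here. How the authors made this scaling is not given in the sources used here. The lowest deposited ratio was 0.01. A gene silent in every sample and a gene equally active in every sample both sit near 1, so the ratios hold no expression level, and a high ratio says only that an array exceeded most of the reference arrays. Tests of single genes compared arrays within a probe. Ratios were set side by side between probes in choosing the probe of a gene, a choice that favours probes with high ratios. They were also compared between genes in the tests of gene lists, the random lists and the correlation between arrays described below.

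The table listed 35557 probes, of which 6701 were blank on every array and 28856 had values. The platform annotation gave 1 symbol to 21789 of the probes with values, several to 1621 and none to 5446. Symbols were checked by Entrez identifier against a RefSeq gene table of assembly GRCm38.p6, used for names alone, which matched 21698 probes and changed 0 symbols. No genome of the build mm9 was given, and no coordinates are printed. Probes with several symbols or none were left out of the gene analysis, and a separate fit of these 7067 probes with limma passed 0 of them in any comparison. The probe with the highest mean stood for each gene, which gave 19938 genes, 999 of them with several probes. All 11 columns were matched to a sample, and 0 columns were left unmapped.

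Log2 of the ratio was taken without a pseudocount, since no value was 0. Log2 intensities had been expected when the design was fixed, so taking log2 was the change that the ratios required. The 3 group means were fitted together over all 11 arrays with lmFit and eBayes with an intensity trend in limma 3.58.1 under R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method over the 19938 genes of each comparison, with a two-sided threshold of 0.05. The trend has no intensity to follow in ratios, and the prior variance it gave ran from 0.00165 to 4.6e+15 between genes, so the fit without the trend is given beside it. A moderated F test asked which genes differed among the 3 tissues, and a gene counted as higher in a tissue than in both others when both comparisons passed. Because such comparisons share arrays, 50 data sets of unchanged groups were simulated for that overlap.

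The comparisons, the tests, the alternatives, 33 gene lists and the rule for named genes were fixed before the data were examined. The lists cover neural crest specifiers, neural plate border genes, crest migration receptors, pan-neural, brain and hindbrain genes, somite and cranial mesoderm genes, epithelial and mesenchymal genes, Wnt, FGF, BMP, retinoic acid, Notch and hedgehog genes, posterior Hox, pluripotency, neuron, melanocyte and glia, cartilage, cell cycle and glycolysis genes. Further lists hold markers of surface ectoderm, endothelium, primitive erythrocytes, gut endoderm, notochord, cardiac, lateral plate and placode cells, stress response genes and ubiquitous genes. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 33 lists of each comparison. Per comparison, the rule named the 10 largest differences each way among genes that passed with no overlap between groups, or, where fewer than 5 passed, the 5 with the smallest p each way. It also named up to 4 members of each list and 15 tissue genes such as Sox10, Pax6 and Meox1. Predicted genes were not named by it. Genes outside the rule are said to have been picked after their values were seen.

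After the values were seen, a gene was called high or low on an array when it lay at least 4-fold from its reference. Random lists of the same size, 10000 per array, gave the chance of a list's count of high members. Similarity between arrays was the Pearson correlation over genes, and its mean within tissues was compared with that between tissues by a two-sided test of 100000 permutations of the tissue labels, a test also added after the values were seen.

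The alternatives were the replicate number as a block, quantile normalization, subtraction of array medians, no trend, a robust variance prior, array weights, the mean of a gene's probes, only the compared pair of groups in the fit, a minimum log2 difference of 1, and leaving out each array in turn. A filter on dim probes had been planned and was not run, since ratios hold no level. A block for arrays outside the reference median, a filter on variable genes, removal of 2 paraxial mesoderm arrays with markers of other cell types, and lists without Snai1 and Epcam were added after the values were seen. The residual SD under the block for arrays outside the reference was set against 30 blocks of 1 neuroepithelium and 2 neural crest arrays, itself included. Splits of the arrays into groups of the same sizes were refitted, at most 100 per result with the real grouping included.

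The fits were tested on simulated data of 19938 genes with the measured spread, in which 50 genes of each kind were raised. Among genes near their reference on every array, 100% of those raised by log2 2 or 5 were recovered in each comparison. These genes were picked for a small spread, so this recovery was all but fixed in advance. A measured gene raised that far would itself count among genes at least 2-fold off. Among genes at least 2-fold off somewhere, the fit with the trend recovered 14% at log2 2 and 40% at log2 5 for neural crest against neuroepithelium. For neural crest against paraxial mesoderm it recovered 4% and 42%, and for paraxial mesoderm against neuroepithelium 6% and 34%. It called 9, 10 and 6 unchanged genes in the same order. All kinds were raised together in one data set, and the recovered genes near their reference eased the Benjamini-Hochberg adjustment for the others. Few genes passed in the measured data, so these recoveries may overstate what the fit could find there. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.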

Results

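Expression was compared among neuroepithelium (n = 3 arrays), neural crest (n = 5) and paraxial mesoderm (n = 3), all captured from mouse embryos at E8.5. Each value is the deposited ratio of an array to the gene's own reference, so a high ratio places an array above most others and gives no expression level. The number of arrays limits the precision of every comparison. How the captured cells were chosen, and how many cells or which embryo stand behind an array, are not given in the sources used here.

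Most genes stayed close to their reference on every array. Of 19938 genes, 14316 (71.8%) lay within 2-fold of it on all 11 arrays, among them the neural regulators Sox1, Sox3 and Pax6, the somite and mesoderm regulators Meox1, Tcf15, Foxc1, Foxc2 and Tbx1, and the crest factors Tfap2a and Ets1. Actb and Eef1a1 also stayed there. The remaining 5622 genes were at least 2-fold off on some array, above or below their reference. Several were high on 1 array of a tissue and not on its fellows. Neuroepithelium array 3 was high for Otx2 (112) and Pou5f1 (45.4), paraxial mesoderm array 2 for Pou5f1 (106), Krt19 (65.0) and Pitx1 (17.3), and paraxial mesoderm array 3 for the ventral neural gene Nkx6-1 (36.5) and the notochord genes Nog (9.63) and Foxa2 (7.64). The Y-linked gene Eif2s3y was high on neural crest arrays 1 (132) and 5 (12.8), whereas Xist and Kdm5d stayed near 1 throughout. Krt19, Nog and Eif2s3y are among genes picked after their values were seen, as was the 4-fold limit for a high gene.

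The number of genes at least 4-fold high ran from 381 on paraxial mesoderm array 3 to 1617 on paraxial mesoderm array 1. Group means were 812 ± 279 (SD) for neuroepithelium, 909 ± 483 for neural crest and 934 ± 628 for paraxial mesoderm, so the arrays of a tissue spanned a wider range than the tissue means. Genes at least 4-fold low numbered 219 ± 163, 216 ± 186 and 260 ± 175. Pooled over the tissues, arrays of the same tissue were hardly more alike than arrays of different tissues: the mean correlation was 0.149 over 16 pairs and 0.138 over 39 pairs (difference 0.0111, permutation p = 0.612, 100000 permutations). The tissues differed in this, which was not tested. Every crest array had a higher mean correlation with its own tissue than with the others (0.0800 to 0.243 against 0.0711 to 0.229). Every mesoderm array had a lower one (0.0227 to 0.0799 against 0.0834 to 0.184). The neuroepithelium arrays had 0.146, 0.149 and 0.153 against 0.117, 0.148 and 0.161. Single pairs ran from -0.00703 to 0.367. The labels tie no array to an embryo, and this p may be too small if arrays of one tissue shared embryos.

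**Figure D1:**
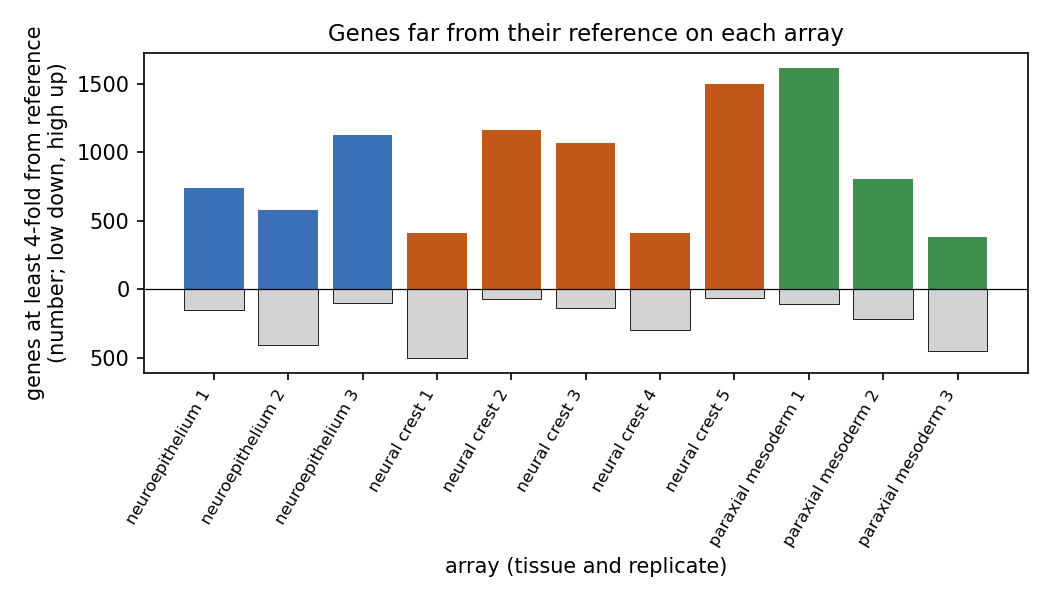
Bars give, for each of the 11 arrays, the number of genes at least 4-fold above (up) or below (down, grey) their reference. The high genes run from 381 to 1617, both on paraxial mesoderm arrays.

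Neural crest was first compared with neuroepithelium, the epithelium from which crest cells leave. Epcam (probe 10447383), an adhesion molecule of epithelial cells, was 39.9-fold lower in neural crest, with ratios of 41.9, 38.8 and 37.4 on the neuroepithelium arrays and 0.944 to 1.03 on the crest arrays (log2 difference -5.32, SE 0.49). Ypel1 (probe 10433953), a gene of the yippee-like family, was lower by a similar amount (24.0, 40.3 and 30.1 against 0.749 to 1.11, log2 difference -5.09, SE 0.43). In the other direction, Snai1 (probe 10478884), a repressor that drives cells out of epithelia, had ratios of 51.0, 47.0, 82.1, 54.9 and 41.2 on the crest arrays and 0.800 to 1.16 on the neuroepithelium arrays (log2 difference 5.78, SE 0.66). The RNA helicase Ddx47 (probe 10542321) stood with it, with a log2 mean of 5.20 ± 0.94 (SD) on the 5 crest arrays, up to a ratio of 108 on array 4, and ratios of 0.981 to 1.02 on the neuroepithelium arrays (log2 difference 5.20, SE 0.80).

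Epcam and Ypel1 passed in limma (adjusted p = 0.0127 for both, all 3 neuroepithelium arrays above all 5 crest arrays; over 22 settings 5.7e-11 to 1 for Epcam and 9.2e-06 to 1 for Ypel1). Each passed in only 9 of the 22 settings. A second Ypel1 probe showed no such difference (group mean log2 ratios 0.37 in neuroepithelium and -0.11 in crest), and the mean of both probes differed by -2.79. Snai1 and Ddx47 did not pass with the intensity trend (limma adjusted p = 0.0585 and 0.269), although all 5 crest arrays exceeded all 3 neuroepithelium arrays by log2 5.78 and 5.20 on average. Without the trend they passed at 9.2e-06 and 0.00626, in a range over the settings from these values to 1. Snai1 passed in 4 of the 22 settings and Ddx47 in 1. The labels tie no array to an embryo, and these p-values are too small if arrays of one tissue shared embryos.

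**Figure D2:**
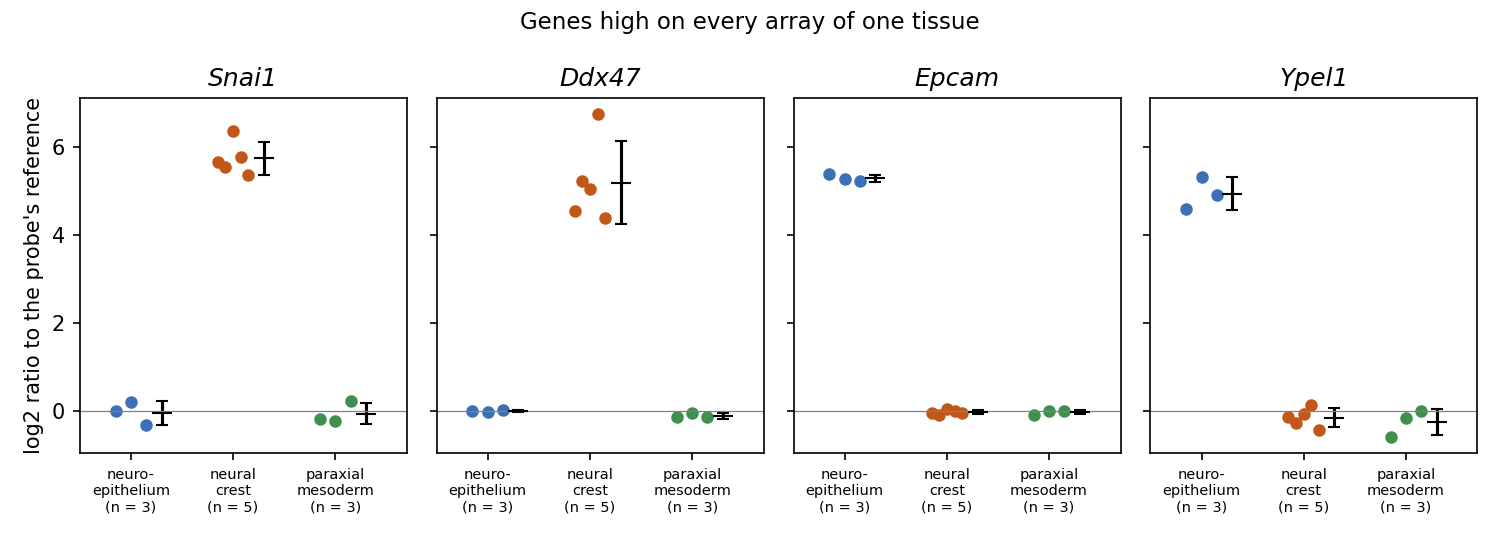
Points give the log2 ratio to the gene's reference on each array for Snai1, Ddx47, Epcam and Ypel1, with group mean and SD for neuroepithelium (n = 3), neural crest (n = 5) and paraxial mesoderm (n = 3). Snai1 averages 5.75 in neural crest and -0.04 in neuroepithelium, and Epcam 5.30 in neuroepithelium and -0.02 in neural crest.

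Neural crest specifiers were higher in neural crest as a list. Of 18 measured transcription factors 15 had a positive difference (mean log2 1.31, median 0.88), 0 passed over all genes, and Snai1 and Myc (log2 difference 5.51, SE 0.90) passed when adjusted over the list alone. The list passed in limma's camera (adjusted p = 1.5e-07, and 0.0154 with an estimated correlation; range over 21 settings 1.5e-08 to 0.0537, the highest without Snai1 and with an estimated correlation together). High on at least 1 crest array were 10 of the 18, and 7, such as Tfap2a and Ets1, stayed within 2-fold on every array. Of the 10, Snai1 alone was high on all 5 crest arrays. Sox9 was high on crest arrays 2 (17.2) and 5 (21.3), Tfap2b on arrays 2, 3 and 5 (27.9, 21.4 and 51.3), Lmo4 on the same arrays (10.8, 85.6 and 98.3), Twist1 on arrays 2 (8.79) and 5 (27.3), and Nr2f1 on arrays 3 (10.5), 4 (4.91) and 5 (17.9). Sox10, a crest factor kept from early migration onward, reached 7.67 on array 5 and 1.10 to 2.69 on the other crest arrays (log2 difference 1.38, SE 0.54, limma adjusted p = 1, all 5 crest arrays above 1). Foxd3 was highest on crest array 4 (3.99). The count of specifiers high on each crest array was 2, 6, 5, 2 and 9, against 1 on every neuroepithelium array (Id2, Twist1 and Tfap2b in turn). Random lists of the same size reached these counts at p = 0.0531, 0.0005, 0.0019, 0.0532 and 0.0001 (permutation of genes, the last the smallest possible). All such p-values measure these arrays only, since the embryos are not tied to them.

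Epithelial junction and polarity genes were lower in neural crest. The mean log2 difference over 21 genes was -1.32 (median -0.26), 2 genes had a positive difference, Epcam passed over all genes, and Cldn7 (log2 difference -5.94, SE 1.48), Crb3 (-3.51, SE 1.02) and Epcam passed when adjusted over the list alone. The tight-junction gene Cldn7 had ratios of 67.6, 57.5 and 42.0 in neuroepithelium and 0.819 to 1 in crest. Cldn4 was high on neuroepithelium arrays 1 (39.2) and 2 (69.6), Crb3 on arrays 1 (43.9) and 3 (26.9), Cldn6 (14.3) and Grhl2 (25.0) on array 3 alone. No member was high on any crest array. Camera in limma gave adjusted p = 1.9e-09 for the list (0.0412 with an estimated correlation; range over 21 settings 4.4e-13 to 0.113, the highest without Epcam and with an estimated correlation together), with 8 genes high on at least 1 of the 3 neuroepithelium arrays. The p-values are too small if the arrays of one tissue, which the labels tie to no embryo, shared embryos.

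Some keratins were high on the same arrays as the epithelial genes. The surface ectoderm markers Krt18 (91.6, 72.4 and 78.6) and Krt8 (35.2, 34.0 and 33.9) were high on all 3 neuroepithelium arrays. Krt18 lay at 0.863 to 1.04 on the crest arrays (log2 difference -6.46, SE 1.46), whereas Krt8 reached 36.3 on crest array 3. Krt8 was also high on mesoderm arrays 2 (34.4) and 3 (30.5). On crest array 3 and mesoderm array 3 no gene of the epithelial list was high. Grhl3 and Wnt6 (15.0), both surface ectoderm genes, were high on neuroepithelium array 2. The list of 12 had a mean of -1.15 (median -0.07), 4 genes were positive, Krt18 passed when adjusted over the list alone, and the list did not pass in limma's camera (adjusted p = 0.0678, 0.901 with an estimated correlation, 0.950 by fry) over these arrays of unknown embryos. Msx1, a gene of the neural plate border, was high on all 3 neuroepithelium arrays (24.7, 46.1 and 7.97) and on crest array 3 (32.3).

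**Figure D3:**
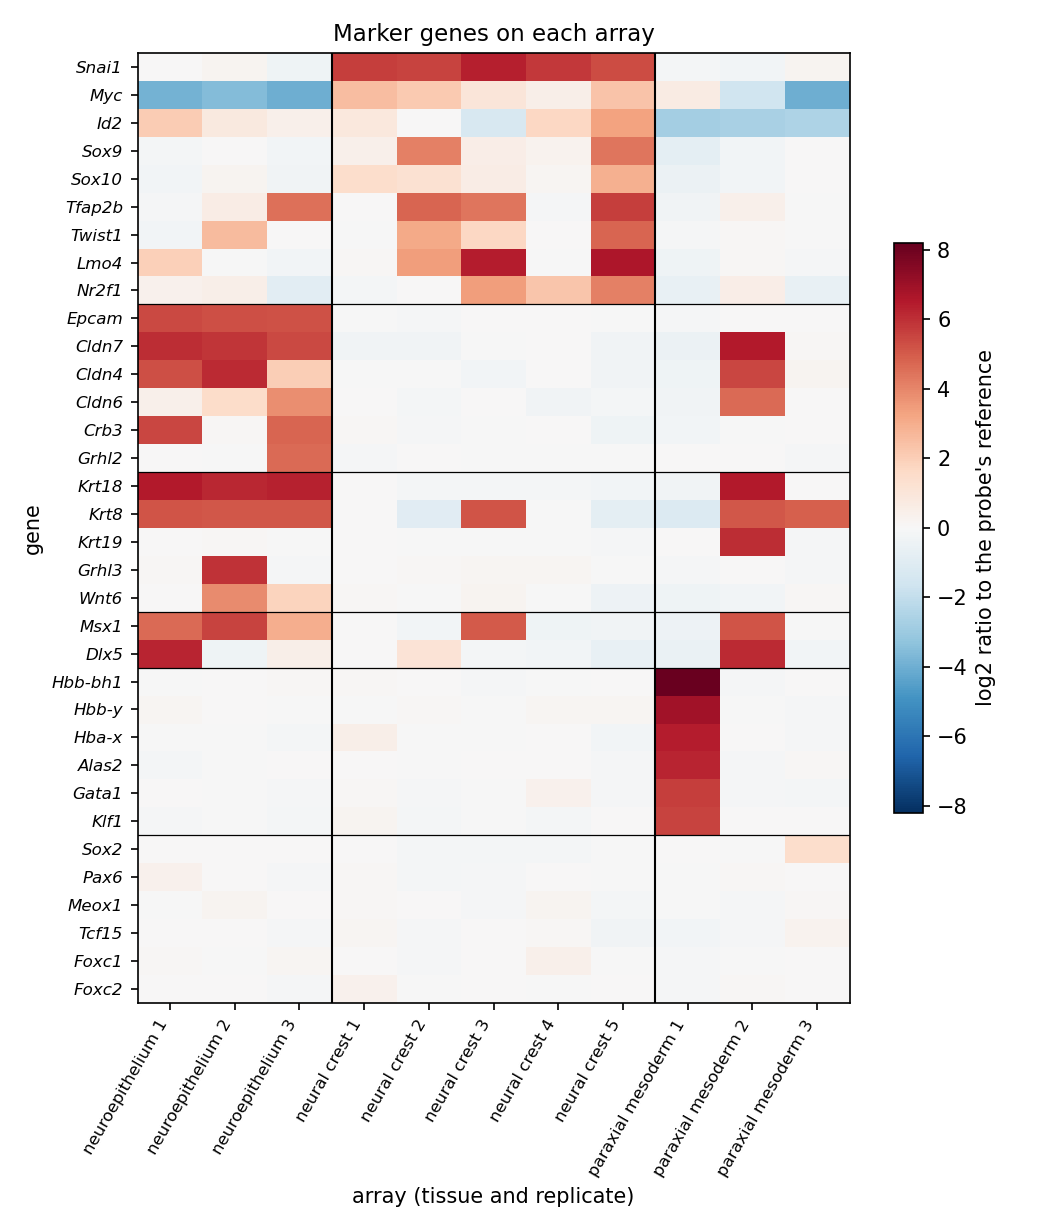
Colour gives the log2 ratio of 34 genes (lines) on 11 arrays (columns, by tissue). Epcam, Krt18 and Cldn7 are high on every neuroepithelium array and Snai1 on every neural crest array, while Sox9, Tfap2b and the globin genes are high on some arrays of a tissue only.

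Further genes separated the tissues without passing. Myc (probe 10424400), a growth regulator also used by crest, had ratios of 0.0687, 0.0836 and 0.063 in neuroepithelium and 1.42 to 5.83 in crest. Mtap (0.108 to 0.137 against 1.23 to 8.57, log2 difference 4.82, SE 0.99) and the lysosomal gene Lamp1 (0.0519 to 0.0729 against 0.411 to 4.64, log2 difference 4.39, SE 0.93) shared this shape. Higher in neuroepithelium were Anxa7 (16.0, 13.5 and 6.30 against 0.76 to 1), the mitochondrial gene Aifm1 (5.07, 10.5 and 15.4 against 0.488 to 1), and Mfsd10 (3.78, 12.7 and 4.31, log2 difference -2.55, SE 0.37). Their adjusted p in limma was 0.328 for Myc, 1 for Mtap and Lamp1, 0.0585 for Anxa7 (log2 difference -3.68, SE 0.44), 0.328 for Aifm1 and 0.222 for Mfsd10, each with no overlap between the 5 and 3 arrays.

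Over all genes 0 were higher and 2 lower in neural crest by limma. At unadjusted p < 0.05 there were 579 genes, where evenly spread p-values would give 997 of 19938. The shortfall shows that the p-values are not spread evenly, so 997 is no measure of chance here. Its cause was not tested. Without the trend 2 were higher and 4 lower (557 unadjusted), the additional ones being Snai1, Ddx47, Anxa7 and the predicted gene Gm5617. Leaving out 1 array moved the count of 2 to between 0 and 12: it was 8, 12 and 12 without neuroepithelium arrays 1, 2 and 3, 4 without mesoderm array 2, and 0 without mesoderm array 1 or 3 or any of the 5 crest arrays. Genes with no overlap between the groups made up 2.98% (289 higher and 306 lower in crest), against 3.57% for groups of these sizes by chance. The labels tie no array to an embryo, so these counts measure the spread between these arrays.

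Neural crest was next compared with paraxial mesoderm, the tissue through which crest cells migrate. Snai1 was again far apart, with 0.856 to 1.17 on the mesoderm arrays (log2 difference 5.80, SE 0.66), as was Ddx47 (0.907 to 0.975, log2 difference 5.30, SE 0.80). The imprinted gene Mest lay at 1 to 1.46 on all crest and neuroepithelium arrays and at 0.01, 0.102 and 0.363 in paraxial mesoderm (log2 difference 4.07, SE 0.90). The ratio of 0.01 is the lowest deposited, and the difference was 2.64 without mesoderm array 1 and 5.23 without array 3. Id2, a dominant-negative helix-loop-helix gene used by crest, was 0.146, 0.161 and 0.172 in paraxial mesoderm and 0.404 to 9.71 in crest (log2 difference 3.56, SE 0.88). Clptm1l was higher in mesoderm (6.98, 1.94 and 9.77 against 0.146 to 0.360, log2 difference -4.39, SE 0.67).

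No gene passed this comparison on all arrays. In limma 0 genes were past the threshold, with 588 at unadjusted p < 0.05 against 997 for evenly spread p-values. Without the trend 2 were higher (577 unadjusted), namely Snai1 and Ddx47. With 1 array left out 0 to 35 genes passed, 3, 10 and 35 of them without mesoderm arrays 1, 2 and 3 and 0 without any other. The adjusted p in limma for Snai1 was 0.172 with the trend and 2.7e-05 without it (range over 22 settings from that value to 1), with all 5 crest arrays above all 3 mesoderm arrays by log2 5.80. For Ddx47 it was 0.603 with the trend and 0.0132 without (range 0.0132 to 1), again with no overlap and log2 5.30. Snai1 passed in 3 of the 22 settings and Ddx47 in 1. Mest and Id2 gave adjusted p = 1 and Clptm1l 0.603 in limma, with no overlap between 5 and 3 arrays and the differences given above. The smallest p also fell to genes with slight differences, Phf13 (0.51) and H1f8 (0.18) higher and Snrnp200 (-0.44), Slc16a1 (-0.45), Sbk3 (-0.18) and Ippk (-0.16) lower in crest, none of which passed. Etfa, an electron transfer flavoprotein, was high on the mesoderm arrays (28.0, 19.2 and 37.1) and on crest array 2 (13.8). Non-overlapping genes made up 2.66% (291 higher, 240 lower; 3.57% by chance). With no embryo named for any array, the p-values are too small if arrays of one tissue shared embryos.

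Crest specifiers were higher here too. Of 18 genes 17 had a positive difference (mean log2 1.60, median 1.16), 0 passed over all genes, and Id2, Myc (log2 difference 3.36) and Snai1 passed when adjusted over the list alone. Myc overlapped between the tissues (1.57, 0.318 and 0.0636 in mesoderm, lowest 1.42 in crest), and its difference was 2.20 without mesoderm array 3 and 4.52 without array 1. No specifier was high on any mesoderm array. In limma's camera the list had adjusted p = 1.1e-10 (0.00425 with an estimated correlation; range over 21 settings 1.4e-11 to 0.0121) over 5 and 3 arrays that the labels tie to no embryo. Sox9 differed by 2.30 on average, carried by crest arrays 2 and 5. Vimentin (Vim), an intermediate filament of mesenchymal and neural cells, had 2.49 to 5.76 on the crest arrays and 0.0526, 0.0598 and 5.18 in mesoderm (log2 difference 4.01, SE 1.48).

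Genes of primitive red blood cells were high on paraxial mesoderm array 1 and nowhere else. The embryonic globins Hbb-bh1 (269), Hbb-y (120) and Hba-x (85.5) stood there with the haem enzyme Alas2 (76.6) and the erythroid regulators Gata1 (50.9) and Klf1 (46.6), and 8 of the 10 measured markers were high. The list was lower in crest than in mesoderm (mean log2 -1.61, median -1.85, 0 of 10 positive) with limma's camera at adjusted p = 2.7e-05, but 0.950 with an estimated correlation and 0.967 by fry. Over its 19 settings the adjusted p ran from 4.4e-08 to 0.967. The call rests on 1 of 3 mesoderm arrays, 0 members passed over all genes or over the list alone, and the labels name no embryo.

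Paraxial mesoderm was last compared with neuroepithelium, the remaining pair of tissues. Epcam was lower in mesoderm (0.947 to 1.00 against 37.4 to 41.9, log2 difference -5.32, SE 0.54), and so was Ypel1 (0.667 to 1 against 24.0 to 40.3, log2 difference -5.19, SE 0.48), although its second probe averaged 0.37 in neuroepithelium and -0.18 in mesoderm and the mean of both probes differed by -2.87. They passed in limma (adjusted p = 0.0332 for Epcam and 0.0300 for Ypel1, all 3 arrays against all 3; over 22 settings 1.5e-10 to 1 and 3.1e-05 to 1). Each passed in only 8 of the 22 settings. Anxa7 (log2 difference -3.20, SE 0.49), Mfsd10 (-2.72) and Sinhcaf (-4.20, SE 0.71), a part of a histone deacetylase complex, were lower without passing (limma adjusted p = 0.384, 0.384 and 0.681, each with no overlap of 3 and 3 arrays). Etfa (5.01, SE 1.12) and Clptm1l (3.87, SE 0.75) were higher in mesoderm on every array, Snrnp200 (0.46), Glipr1 (0.39) and Dcaf1 (0.33) slightly so, and none of these passed. Mest (-3.85) and Id2 (-3.75) were lower in mesoderm, whereas Lamp1 (4.58) and Mtap (3.06) were higher, also without passing.

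In all 0 genes were higher and 2 lower in mesoderm by limma, with 520 at unadjusted p < 0.05 against 997 for evenly spread p-values. Without the trend 0 were higher and 3 lower (495 unadjusted, with Gm5617 added). With 1 array left out the count of 2 became 0 to 29: 6, 10 and 8 without neuroepithelium arrays 1, 2 and 3, 3, 3 and 29 without mesoderm arrays 1, 2 and 3, and 0 without any of the 5 crest arrays. Epcam and Ypel1 did not pass without mesoderm array 1 or 2. Non-overlapping genes made up 6.85% (563 higher, 802 lower), against 10% by chance. With no embryo tied to an array, these p-values too describe only the arrays at hand.

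Epithelial genes were lower in mesoderm as a list, and paraxial mesoderm array 2 was the exception. The mean log2 difference over 21 genes was -1.02 (median -0.22), 3 genes were positive, and Epcam alone passed, over all genes and over the list. Limma's camera gave adjusted p = 2.5e-05 on 3 against 3 arrays, and adjusted p = 0.411 with an estimated correlation. Over 21 settings it ran from 2.2e-08 to 0.919. Mesoderm array 2 was high for Cldn7 (92.2), Cldn4 (45.1) and Cldn6 (25.1), together with Krt18 (88.8), Krt8 (34.4), Krt19 (65.0), Msx1 (34.9), Dlx5 (70.4) and Bmp4 (19.4), genes of surface ectoderm and the neural plate border, while Epcam stayed near 1 there. Erythroid markers were higher in mesoderm (mean log2 1.67, median 1.90, all 10 positive, 0 passing alone), which came from mesoderm array 1 (limma's camera adjusted p = 2.5e-05, 0.919 with an estimated correlation, 0.973 by fry; range over 19 settings 7.3e-08 to 0.973). The crest specifiers (mean -0.29, adjusted p = 0.594) and surface ectoderm markers (mean -0.72, adjusted p = 0.201) did not pass in limma's camera, with 4 of 18 and 4 of 12 genes positive. As before, no embryo is tied to an array.

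Across all 3 tissues, 3 genes differed in the F test of limma: Ypel1 (adjusted p = 0.0249), Epcam (0.0251) and Snai1 (0.0448). For Ypel1 and Epcam all 3 neuroepithelium arrays lay above the other 8 (group mean log2 ratios 4.94 and 5.30), and for Snai1 all 5 neural crest arrays lay above the other 6 (5.75). Without the trend 6 passed, with Ddx47 (0.00449), Gm5617 (0.00447) and Anxa7 (0.0355) added. With 1 array left out 0 to 28 passed: 4, 11 and 8 without neuroepithelium arrays 1, 2 and 3, 3, 14 and 28 without mesoderm arrays 1, 2 and 3, and 0 without any crest array. Epcam and Ypel1 were higher in neuroepithelium than in both other tissues (2 genes, 0 in simulations of unchanged groups and 0.000201 by independent overlap). The simulations drew each gene from a normal spread, and the independent overlap ignores the shared neuroepithelium arrays. Neither value can therefore exclude chance. The other classes held 0 genes by limma, so that 0 were higher in neural crest than in both. Without the trend these were 2, Snai1 and Ddx47, and splitting the 5 crest arrays so that the comparisons shared none gave 0 with the trend and 1 to 2 without. By size alone, Snai1 and Ddx47 were at least 4-fold high on every crest array and less than 2-fold above their reference elsewhere. Epcam and Ypel1 were so for neuroepithelium, and 0 genes for paraxial mesoderm. The measure was set after the values were seen and also counts genes that were low elsewhere. With 1 array left out these counts ran over 2 to 6, 2 to 12 and 0 to 27: 6 for crest without crest array 1, 10, 12 and 10 for neuroepithelium without its arrays 1, 2 and 3, 4 without crest array 5 and 5 without mesoderm array 2, and 4, 13 and 27 for mesoderm without its arrays 1, 2 and 3. Mesoderm also had 1 without neuroepithelium array 1 or crest array 5 and 2 without crest array 2. Splits of the arrays, the real grouping included, reached the neuroepithelium count in 38 of 100 and the crest count in 6 of 100. Arrays of one tissue from shared embryos would make these p-values too small.

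The paraxial mesoderm and somite genes (23 measured) and the posterior Hox genes (14), the melanocyte and glia (8), the cartilage and bone (9) and the endothelial genes (12) stayed within 2-fold of their reference on every array. The lateral plate genes (10) had 0 high members. High members were few among hindbrain genes (1 of 9, Fgf3 on mesoderm array 1), anterior brain genes (1 of 17, Otx2), gut endoderm (1 of 12, Foxa2), cardiac mesoderm (1 of 12, Myl7 on neuroepithelium array 2, log2 5.26), cranial placode (1 of 7, Eya2 on mesoderm array 2, log2 4.00) and notochord markers (2 of 6, Nog and Krt7). Cranial mesoderm had 3 of 13, with Alx1 (log2 2.60) and Prrx2 (4.33) on crest array 5 and Pitx1 on mesoderm array 2. Pan-neural genes had 5 of 22, with Fabp7 on crest arrays 4 (95.4) and 5 (63.0) and Irx3 on neuroepithelium array 3 (10.1). Plate border genes had 5 of 13, with Wnt1 on crest array 2 (log2 5.04), and migration receptors 3 of 23, with Crabp1 on neuroepithelium arrays 1 and 2 (log2 3.70 on array 2) and crest arrays 2 and 5 (4.14 and 2.46).

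Signalling targets showed a few genes on several crest arrays. Spred2, an inhibitor of ERK signalling, was high on crest arrays 2 to 5 (4.19, 7.64, 10.4 and 30.6), with a second probe near its reference, and the Wnt inhibitor Nkd1 on arrays 2 to 4 (22.3, 36.9 and 43.6). High members numbered 3 of 13 for Wnt targets, 2 of 11 for FGF-ERK targets, 1 of 10 for BMP targets (Bambi), 3 of 12 for retinoic acid genes (Crabp2, Rdh10, Rara), 2 of 13 for Notch genes (Lfng, Hey2) and 3 of 10 for hedgehog genes (Gli3, Smo, Cdon). Fry passed the FGF-ERK targets against paraxial mesoderm when direction was ignored (adjusted p = 0.0146 in limma, mean log2 0.29 with 7 of 11 positive). High members on arrays of every tissue were found among cell state genes: 8 of 21 mitotic genes, such as Tyms (log2 2.76 on crest array 3, 3.64 on mesoderm array 1) and Bub1 (log2 3.39 on neuroepithelium array 1, 4.06 on crest array 5), 2 of 16 pluripotency genes, 2 of 14 early neuron genes (Tubb3, log2 4.41 to 5.53 on 5 arrays), 2 of 22 mesenchymal genes (Vim and Sparc) and 7 of 13 ubiquitous genes. The 2 of 13 glycolysis genes (Slc2a3 and Pfkl) and 4 of 14 stress response genes such as Ier2 that were high were so on neuroepithelium or crest arrays and on 0 mesoderm arrays. Hprt, a housekeeping gene, ran from 0.291 on crest array 1 to 45.3 on crest array 5.

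None of these 29 lists passed in limma's camera, and 0 of their members passed over all genes or, with the trend, over the list alone. Without the trend 1 FGF-ERK target was lower in crest than in mesoderm when adjusted over the list alone. Over the lists that did not pass, adjusted p ran from 0.0678 to 0.910 for neural crest against neuroepithelium, 0.364 to 0.964 against paraxial mesoderm and 0.0785 (stress response, mean log2 -0.57, 3 of 14 positive) to 0.974 for paraxial mesoderm against neuroepithelium, on 3 to 5 arrays per tissue that are tied to no embryo. In some of them median, mean and test differed in sign, all with medians near 0: in crest against neuroepithelium the mesenchymal, Wnt, BMP, glycolysis, mitotic, pluripotency, somite, cartilage, anterior brain, migration, early neuron, notochord, lateral plate and placode lists. Against mesoderm these were the plate border, pan-neural, brain, hindbrain, BMP, hedgehog, pluripotency, mitotic, notochord, cardiac and placode lists, and in mesoderm against neuroepithelium the brain, hindbrain, cranial mesoderm, Wnt, FGF-ERK, BMP, Hox, melanocyte and glia, and gut lists. Lists that passed had the same sign in all 3 measures.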

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

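The rule below was fixed before the data were examined, whereas many of the genes it ran on were picked for the text after their values had been seen.

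A single neural crest array stood apart from the other 4 in 6 of 29 genes under a Dixon test, where 1.45 would be found by chance at 1 in 20. Krt8, a keratin, had a ratio of 36.251 on neural crest array 3 against 0.525 to 1 on the others, and the plate border gene Msx1 had 32.269 on the same array against 0.796 to 1. Nes, which encodes a filament of neural progenitors, had 8.482 there, against 0.897 to 1.01. The pluripotency gene Pou5f1 had 32.589 on array 4 against 0.913 to 0.975, the flavoprotein gene Etfa 13.845 on array 2 against 0.810 to 1.03, and Otx2 3.613 on array 1 against 0.962 to 1.02. Array 3 held 3 of the 6. A Dixon test assumes a normal spread, and genes chosen for their values make such flags more frequent, so the count does not tell a fault of an array from values that vary from array to array. No array was left out.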

How the results depend on the processing

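The alternatives were fixed before the data were examined, except those said to be added. The counts of genes past the threshold are given in the order crest against neuroepithelium, crest against mesoderm, mesoderm against neuroepithelium, F test, and higher in crest than in both, and were 2, 0, 2, 3 and 0 as reported. Where they moved, the cause was not tested. The replicate number as a block gave 0, 0, 0, 0 and 0, and same-numbered arrays did not deviate together (r = -0.153 to 0.0505). Arrays of one tissue correlated at only 0.149 on average, so a shared embryo could go unseen. Whether the numbers pair arrays therefore stays open. Quantile normalization gave 3, 1, 0, 1 and 1, no trend 6, 2, 3, 6 and 2, the robust variance prior 0 in all 5, array weights 6, 0, 2, 4 and 0, the mean of probes 2, 0, 2, 2 and 0, and only the 2 groups compared 0, 0, 0 and, for genes higher in crest than in both, 0. Subtracting medians and asking for a log2 difference of 1 changed no count. A filter on dim probes was not run, since ratios hold no level.

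Leaving out 1 array at a time gave 0 to 12, 0 to 35, 0 to 29, 0 to 28 and 0 to 0. Without neuroepithelium array 1 the first 4 counts were 8, 0, 6 and 4, without array 2 12, 0, 10 and 11, and without array 3 12, 0, 8 and 8. Without any of neural crest arrays 1, 2, 3, 4 or 5 all were 0. Without mesoderm array 1 they were 0, 3, 3 and 3, without array 2 4, 10, 3 and 14, and without array 3 0, 35, 29 and 28. Of the alternatives added after the values were seen, a block for arrays outside the reference and a filter on variable genes gave 0 in all 5, and removal of mesoderm arrays 1 and 2 gave 1, 197, 166, 164 and 0, with the lone mesoderm array taken to vary like the other groups. Genes high on every array of a tissue and less than 2-fold above reference elsewhere numbered 2 for crest, 2 for neuroepithelium and 0 for mesoderm. Low values elsewhere were allowed. With 1 array left out the counts ranged over 2 to 6, 2 to 12 and 0 to 27. Crest gave 6 without crest array 1, neuroepithelium 10, 12 and 10 without its arrays 1, 2 and 3, 4 without crest array 5 and 5 without mesoderm array 2, and mesoderm 4, 13 and 27 without its arrays 1, 2 and 3, 2 without crest array 2, and 1 without neuroepithelium array 1 or crest array 5. At 2-fold the neuroepithelium count was 6, and at 8-fold the 3 counts were 2, 2 and 0.

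Over 78 genes, 3 comparisons and all settings, 4940 of 5088 values kept their side of the threshold or, for genes not past it, stayed within 1 SD between arrays, which still lets a difference move widely. Another 49 moved by more, 45 came to pass, 54 no longer passed and 0 reversed, and most of these genes never passed. The erythroid list reversed between crest and mesoderm without mesoderm array 1 (mean log2 0.0176, range -2.43 to 0.0176 over arrays left out; limma's camera adjusted p = 0.908) and without mesoderm arrays 1 and 2 (0.00966, adjusted p = 0.963). With array weights it was weaker (adjusted p = 0.0889, and 0.137 against neuroepithelium), as was the epithelial list between mesoderm and neuroepithelium (mean -0.65, adjusted p = 0.137). Without Snai1 and Epcam, a choice added later, limma's camera gave the crest list adjusted p = 2.1e-05 against neuroepithelium (mean 1.05; 0.0537 with an estimated correlation) and 3.1e-08 against mesoderm (mean 1.36; 0.0121). The epithelial list gave 5.15e-07 in crest (mean -1.12; 0.113) and 0.00144 in mesoderm (mean -0.80; 0.919).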

Other observations

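The tests of whole patterns below, the block for arrays outside the reference and the splits of genes high on every array of a tissue were chosen after the values had been seen, and the other splits were set before.

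Several crest and border genes were shared by particular arrays in ways the comparisons do not describe. Neural crest array 5 alone joined Sox10, Sox9, Twist1 and Tfap2b with Alx1 (log2 2.60) and Prrx2 (4.33), genes of facial mesenchyme, and with the crest cadherin Cdh6 (3.09). Neural crest array 2 carried the dorsal midline gene Wnt1 (5.04) with Sox9 and Twist1, and crest arrays 1 and 4 had Snai1 with few other specifiers. Of the crest arrays, 1 and 4 had the fewest high genes of any kind (410 each) and array 5 the most (1500). Array-wide numbers may thus be all that these combinations reflect, which was not tested for them. Tubb3, a tubulin of young neurons, was high on neuroepithelium arrays 1 and 2 (4.41 and 5.26) and neural crest arrays 2, 3 and 5 (4.44, 5.20 and 5.53). B2m was high on neuroepithelium array 1 (5.45) and on the same 3 crest arrays (4.39, 4.22 and 5.71).

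Metallothionein 1 (Mt1) was high on all 3 neuroepithelium arrays (ratios 12.7, 26.6 and 21.8) and on mesoderm arrays 1 and 2 (25.4 and 24.9), and below its reference on all crest arrays (lowest ratio 0.566). Mesoderm array 3 joined Sparc (log2 5.89) and Ccnd1 (5.68) with Nkx6-1, Nog and Foxa2, genes of the ventral neural tube, notochord and floor plate. All these genes were picked after their values were seen.

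Chance can not be excluded as the source of any gene count that was set against other splits. Splits into groups of the same sizes were counted with the real grouping among them, here and below. At least as many genes came from 13 of 56 for crest against neuroepithelium (2 found, up to 19 in another split), 8 of 56 without the trend (6 found, up to 31), and 34 of 56 against mesoderm without the trend (2 found, up to 29). For the F test it was 43 of 100 (3 found, up to 34), for genes high on every crest array 6 of 100 (2 found, up to 8) and for those high on every neuroepithelium array 38 of 100 (2 found, up to 25). Where 0 genes were found every split reaches the count, so the splits say nothing about chance for crest against mesoderm with the trend (56 of 56, up to 20) and for genes higher in crest than in both (100 of 100, up to 1). Mesoderm against neuroepithelium allows 10 splits, too few for a share under 0.05: 3 gave as many (2 found, up to 5), and 6 without the trend (3 found, up to 8). The split with 25 genes, the highest of its 100, joined neuroepithelium array 3, neural crest array 5 and mesoderm array 1. A structure of the arrays other than their tissues could give such counts, but these are 3 of the 4 arrays with the most high genes (1122, 1500 and 1617), so array-wide numbers may be all that it reflects, and neither was tested.

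Erythroid genes on paraxial mesoderm array 1 may stem from a red blood cell in the capture. Of 10 measured erythroid markers 8 were high there, and 0 members of any other marker list were. An array-wide excess of high genes is an unlikely cause, as random lists reached at most 6 (permutation p = 0.0001 over lists, the smallest possible).

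Epithelial genes on the neuroepithelium arrays are unlikely to reflect an array-wide excess of high genes, since random lists reached as many at a permutation p = 0.0066 or less on each array. Surface ectoderm cells in the captures and the tissue of origin cannot be told apart. Krt8 and Krt18 were high on all 3 arrays, whereas of the 10 other surface ectoderm markers 0, 2 and 0 were high on the arrays in turn. Both keratins were also high on mesoderm array 2, and Krt8 on crest array 3 and mesoderm array 3. Of all 12 markers 6 lay within 2-fold of their reference on every array, which says nothing about their level. Wnt6 reached 3.52 on array 3, short of the 4-fold limit. The count therefore does not decide on such cells for any of the 3 arrays. Of 22 pan-neural genes 14 lay within 2-fold everywhere, and ratios hold no level that could show whether these arrays are neural. A measure of absolute levels for Sox2, Epcam and Krt18 could part these readings.

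Few genes passed between the tissues, which does not mean that few differed. In the simulated data the fit with the trend missed most variable genes even when raised by log2 5 (34% to 42% recovered). Pooled over the tissues, arrays of a tissue were about as unlike each other as arrays of different tissues (difference in mean correlation 0.0111). Crest arrays lay above and mesoderm arrays below that. The correlation reflects the same spread as the tests, so it is no separate explanation. A reference shared by all arrays cancels from each gene's log2 differences and residual SD. The block for arrays outside the reference median therefore bears only on a different scaling of those arrays. Such a scaling is not likely to be the whole cause of the few passing genes, since the block hardly changed the median residual SD over genes. The fall was -1.16% over all genes (up to 9.05% for blocks of other arrays of the same tissues). Over genes at least 2-fold off on some array it was 0.36% (up to 2.67%). Epcam stayed at -5.32, which does not bear on why few genes passed. It no longer passed in limma (adjusted p = 0.0531 for crest and 0.114 for mesoderm against neuroepithelium). Under that block 0 genes passed in any comparison, a count that decides little by itself, as the replicate block and the robust variance prior gave 0 too. Small captures with strong amplification could leave such patchy values, as could real differences between the cells, and the values at hand do not part these. For genes within 2-fold of their reference on every array, such as Meox1 and Pax6, detection was not tested, so differences between the tissues that were lost before measurement stay open.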
